A study of Homo sapiens with 10 samples.

How the data were processed

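Total RNA of 5 human prostate cancer cell lines (C4-2B, DU145, LAPC4, PC3 and VCaP) was profiled after 24 h with (R)-9bMS, an inhibitor of the tyrosine kinase ACK1 (gene TNK2), or with its solvent DMSO. There were 10 arrays, 1 per line and treatment. Per the labels' protocols, lines kept in medium with 10% serum were moved to charcoal-stripped, androgen-deficient medium for 24 to 48 h, then treated with 3.5 uM inhibitor, and 10 ug of RNA was reverse transcribed with a labelled nucleotide. The labels give the Cy5 and the Cy3 channel of an array the same line and the same treatment, and name no reference RNA and no dye swap.

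Each scanner table holds 45015 spots, of which 43376 are not controls and carry 41000 probes of an Agilent human gene expression design annotated on hg18. The mean signal and the background median of each spot are raw intensities, per the file headers, extracted with Feature Extraction 9.5.1.1, while the submitters' processing notes name version 8.5.1.1. The processed signals are intensities that the scanner software had background-subtracted, detrended and dye-normalized within the array, per the file headers. The deposited value table of the series holds log10 ratios, and each of its 10 columns equals the scanner's own log10 ratio of Cy5 over Cy3 spot for spot, with a largest difference of 0 and a column median of 0. So its scale and its dye direction are known, its values are not centred further, and which treatment lies behind either dye beyond what the labels say stays unknown.

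From there, mean signals were corrected with normexp (offset 50), normalized by loess within each array and by Aquantile between arrays in limma 3.58.1 under R 4.3.3, with the data.table package (1.17.8) and jsonlite 2.0.0; figures used Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. Control spots had no weight and were then left out, as were spots that the software marked as outliers, which left 178 probes without a complete set of values. Spots of one probe were averaged. Probe accessions were looked up in a RefSeq table of the GRCh38 assembly, used for names only; 23958 probes were named by accession, 2755 by symbol and 1032 by an older symbol, and 13255 kept the name in the file. Coordinates are those of the array files on hg18, and what part of a gene a probe lies in was not looked up, since no annotation of that build was used here.

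The value of a sample was the mean of its channels on the log2 scale. A rule for the channels was fixed before the data were examined, as were the tests, the gene lists, the rule for the names printed and most of the other settings tried. The median SD of a probe over the arrays was 0.667 in Cy3 and 0.811 in Cy5, so neither channel behaved as a reference common to all arrays. This SD runs over different lines, so it could not show a reference matched to each line. In LAPC4 and VCaP Cy3 matched between the arrays of a line at 0.974 and 0.969, against 0.690 and 0.535 in Cy5. Each array had at least 48.9% of probes well above background in each channel. The rule therefore kept the mean of the channels as labelled. These channel checks, and the correlations between channel profiles in the report, used the log2 processed signals of probes well above background, with each profile's median and each probe's mean removed for the correlations. The rule also asked whether the log ratios of a line's arrays correlate beyond 0.3 once each probe's mean ratio is removed, which would put the channel labels in doubt. This was so in 1 of 5 lines, C4-2B, whereas without removing the means all 5 lines reached 0.3. The arrays labelled DU145 and PC3 matched across these labels, as the results show, so pairs within the labels were a poor test. Without removing the means, the crossed pairs correlated in their log ratios at 0.896 and 0.848, against 0.496 and 0.440 within the labels. Within-array ratios of Cy5 over Cy3 are therefore reported as well, as an addition made after the data were seen, and only as Cy5 brighter or dimmer than Cy3.

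Probes well above background in both channels on at least 2 arrays of a fit were tested, the brightest probe standing for its gene. This left 20734 genes, 14100 with a current symbol and 6634 named as in the file. The 5-line comparison used lmFit and eBayes with the cell line as a block, since DMSO and inhibitor arrays share a line label. Nothing in the labels says that cultures were replicated, so the line is the only replicate, and p-values measure only the spread between these lines, which may be partly technical. For Cy5 over Cy3, C4-2B, LAPC4 and VCaP each gave the mean of its arrays, and the 4 arrays labelled DU145 and PC3 gave 1 further value, because their expression matched across the labels; the 4 values were tested against 0. P-values were adjusted by the Benjamini-Hochberg method, with calls at 0.05.

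In all, 31 gene lists, 29 of them reported, were tested with camera (limma, preset correlation 0.01), again with an estimated correlation, and with fry, which asks whether a list's genes move one way without setting them against other genes. They cover androgen-repressed genes, TNK2 with its partners, the cell cycle, lipid synthesis, stress responses, signalling, differentiation, DNA repair, cell death, organelles, and markers of other cell types and of the lines. List medians per line were set against 10000 random lists of the same size and mean expression (seed 1). Differences within a line rest on 1 array per treatment and were not tested. Counts beyond 2-fold needed both channels. Correlations over genes describe arrays, and genes are not independent replicates.

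Names in the text follow a fixed rule: a fixed set of prostate and ACK1 genes in every comparison, and up to 10 genes in each direction past the threshold with the same sign in all lines. Where too few passed, genes with the lowest p and a log2 change of at least 0.5 were taken and said not to pass. Per line the 5 largest differences in each direction, and up to 4 members of each list that passed were taken. The choice was limited to genes with a current symbol. Some genes, 2 gene lists and comparisons between classes of lines are not reported here.

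The code was tested on simulated data built on 20734 genes with 50 changed genes per fold. With the spread of the 5 lines, the 5-line test recovered 4%, 50%, 92% and 96% of genes changed 1.5-, 2-, 4- and 8-fold. The simulated change was alike in all 5 lines and in the mean of the channels, with independent noise. The real arrays labelled DU145 and PC3 depart from this, so these shares may not hold for them. The test of Cy5 over Cy3 recovered 36%, 96%, 100% and 100%. There too the simulated change was alike in all 4 values, with independent noise, so these shares may not hold for real ratios that differ between lines. In the real fit limma did not call SLC7A11 at 1.45 or MT1G at -1.40. Alternatives changed the background correction, the normalization, the channel, the filter on dim probes, the summary over probes, the variance model, array weights, the block, slide and scan date, and the lines included. The number of arrays limits the precision of every value.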

Results

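Gene expression was measured in 5 prostate cancer cell lines treated with (R)-9bMS, a small-molecule inhibitor of the non-receptor tyrosine kinase ACK1 (gene TNK2), or with DMSO. C4-2B is a castration-resistant derivative of LNCaP, and the other 4 are lines from metastases. The 10 arrays, 1 per line and treatment, lay on 4 slides scanned on 3 dates. Cy3 showed 49.4% to 63.4% of probes well above background per array and Cy5 48.9% to 75.7%, at median raw intensities of 68.7 to 149 and 78.9 to 166. The number of arrays limits the precision.

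Marker genes did not follow the line labels of DU145 and PC3. HOXB13, a homeobox factor of the prostate lineage, read a log2 intensity of 13.20 on the array labelled DU145 with DMSO and 13.19 on that labelled PC3 with inhibitor, but 6.45 and 6.53 on the arrays labelled DU145 with inhibitor and PC3 with DMSO, where it was not well above background. FKBP5, a steroid receptor cochaperone, split the other way, at 6.59 and 6.56 on the first pair and up to 8.56 on the second. CAV1, caveolin, read 11.67 on both arrays of the first pair and 12.32 and 12.33 on the second, against at most 6.69 in C4-2B, LAPC4 and VCaP.

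Over probes, with each probe's mean removed, the array labelled DU145 with DMSO correlated at 0.933 (Cy3) and 0.935 (Cy5) with that labelled PC3 with inhibitor. The array labelled PC3 with DMSO correlated at 0.920 and 0.927 with that labelled DU145 with inhibitor. The pairs that share a line label reached only 0.155 and 0.149 for DU145 and 0.118 and 0.0917 for PC3. These 4 arrays are therefore named by their labels throughout, and a treatment difference within DU145 or PC3 compares arrays that did not resemble one another. In the other lines the arrays of a line matched closely in Cy3, at 0.985 for C4-2B, 0.974 for LAPC4 and 0.969 for VCaP. In Cy5 they matched at 0.987, 0.690 and 0.535. The Cy3 and Cy5 profiles of one array, which the labels describe as the same RNA, correlated at 0.799 and 0.793 in C4-2B (DMSO, then inhibitor), 0.717 and 0.525 in LAPC4 and 0.747 and 0.554 in VCaP, less than Cy3 with Cy3 between the arrays of the line. These correlations are across probes, which are not independent replicates.

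**Figure D1:**
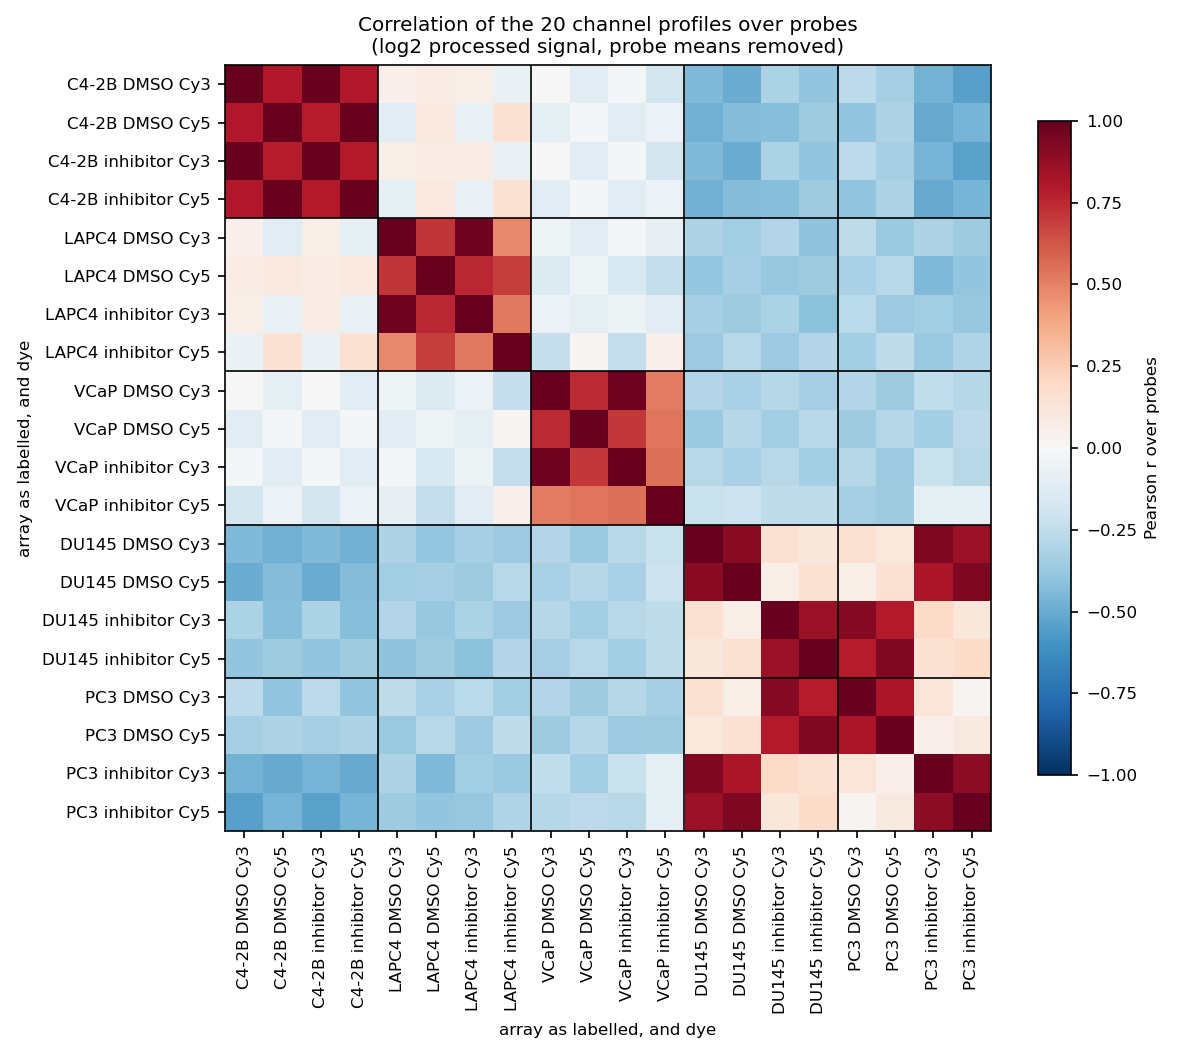
Pearson correlations across probes between the 20 channel profiles (10 arrays, Cy3 and Cy5), with each probe's mean removed; rows and columns are arrays by label and dye, and colour gives r. The array labelled DU145 with DMSO pairs with that labelled PC3 with inhibitor (0.933 in Cy3), while the DU145-labelled arrays correlate at 0.155.

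**Figure D2:**
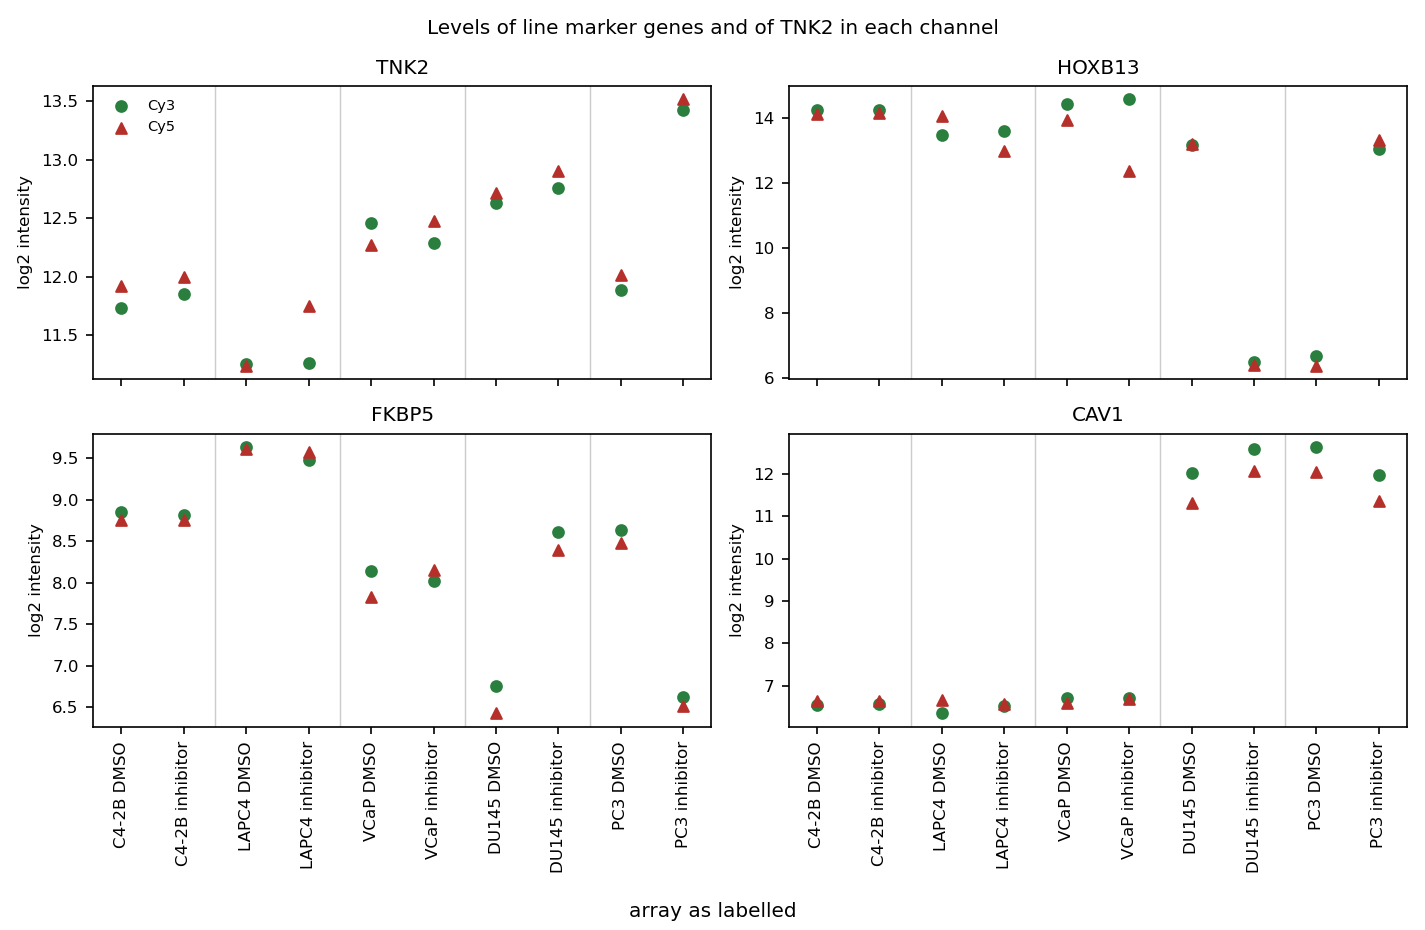
Log2 intensity of TNK2, HOXB13, FKBP5 and CAV1 in each channel of each array, 1 point per channel and array label. HOXB13 is at background on the arrays labelled DU145 with inhibitor (6.45) and PC3 with DMSO (6.53).

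The first comparison asked which transcripts the ACK1 inhibitor changed across the 5 lines, with samples taken as labelled and the channel and line labels in the doubt described. TNK2 itself, whose product the drug blocks, was 0.41 ± 0.24 higher on the log2 scale (SE, 5 lines; limma adjusted p = 1.00), with differences of 0.10 in C4-2B, 0.16 in DU145, 0.26 in LAPC4, 1.52 in PC3 and 0.02 in VCaP. This rests on 1 probe, since a second detected TNK2 probe gave a mean of -0.02, with 0.00, -1.08, -0.13, 0.83 and 0.28 in the same order. A kinase inhibitor need not alter its target's transcript, so this does not check the labels. None of the prostate genes measured singly passed: KLK2, a kallikrein protease, differed by 0.17 ± 0.19 (0.001 by a second probe), TMPRSS2, a serine protease, by 0.22 ± 0.46 and FKBP5 by -0.02 ± 0.52. KLK3, which encodes PSA, stood at 0.16 ± 0.11 by a probe that was as bright under the DU145 and PC3 labels. WDR5 and KMT2D, parts of the complexes that methylate histone H3 at lysine 4, differed by 0.11 ± 0.23 and 0.28 ± 0.12, and HOXB13 by -0.26 ± 1.76 (adjusted p = 1.00 for each).

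No gene of 20734 passed in limma, and 210 had an unadjusted p under 0.05. The spread of this fit includes the labelled differences of DU145 and PC3, which compare arrays that did not match. Without those arrays limma also called 0 genes, with 867 at an unadjusted p under 0.05. So 0 calls do not show that the inhibitor changed no transcript. The genes of lowest p with one sign in all 5 lines were all higher and did not pass: LUC7L, a splicing factor, at 0.72 ± 0.24, IER5L, an immediate early gene relative, at 0.63 ± 0.21, TOMM20, a mitochondrial import receptor, at 0.66 ± 0.23 and FAM43B at 0.77 ± 0.28. KRTAP4-11, IRX4, SEC16B, TOMM20L, WDTC1 and CSDC2 lay between 0.51 and 0.66. Of the 29 lists reported, the G2 and M phase genes fell, with a median of -0.17, 23 of 25 members below 0 and camera adjusted p = 0.0433, but adjusted p = 0.955 with an estimated correlation. None of their members passed adjusted over the list alone. Without VCaP no list passed, while 7 did without DU145. CDC25C, the phosphatase that starts mitosis, differed by -0.45 ± 0.34 and BUB1, a spindle checkpoint kinase, by -0.17 ± 0.13. By label the median was 0.00 in C4-2B, -0.18 in LAPC4 and -0.56 in VCaP, against 0.93 in DU145 and -0.99 in PC3, whose labels are in doubt.

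The other lists did not pass. Androgen-repressed genes had a median of -0.002 (adjusted p = 0.941) and the list of TNK2, its substrates and the H3K4 methyltransferase complex 0.02 (adjusted p = 0.941). S phase genes stood at -0.12, homologous recombination genes at -0.11, histone genes at -0.05, cholesterol synthesis at -0.07, fatty acid synthesis at -0.03 and heat shock genes at -0.10. The integrated stress response stood at 0.16 (adjusted p = 0.197), NRF2 targets at 0.07, hypoxia genes at 0.07, neuroendocrine genes at 0.07, NF-kB genes at 0.04 and markers of blood, endothelial and fibroblast cells at 0.09. Medians within 0.06 of 0 were found for endoplasmic reticulum chaperones (0.01), aryl hydrocarbon receptor targets (-0.02), metallothioneins (-0.03), FOXO and PI3K feedback genes (-0.01), immediate early genes (-0.01), MYC and ribosome biogenesis (-0.01), interferon-stimulated genes (-0.02), TGF-beta targets (-0.02), luminal genes (0.02), basal and mesenchymal genes (-0.004), apoptosis regulators (-0.06), the mitochondrial respiratory chain (-0.04), autophagy and lysosome (-0.03) and the line markers (-0.01). The smallest adjusted p among these lists was 0.164. With slide or scan date as a further block limma again called 0 genes (21 at an unadjusted p under 0.05 with either).

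Within single lines the labelled treatments differed by very different amounts, and no line had a replicate. In C4-2B no gene of 17989 above background was beyond 2-fold in either channel, and the median absolute difference was 0.05 in Cy3 and 0.04 in Cy5. With the channel labels in doubt, this does not show that C4-2B failed to respond to the inhibitor. In LAPC4, SLC7A11, the cystine transporter, was higher with inhibitor by 2.05 (1.25 in Cy3, 2.84 in Cy5), as was CCDC183 by 1.41, while ZFYVE19, an abscission checkpoint protein, was lower (-1.28). These belong to 4 genes beyond 2-fold in both channels, against 4 by Cy3 and 1515 by Cy5 when both channels were normalized together. In VCaP 25 genes were higher and 0 lower in both channels, led by GORASP2, a Golgi stacking protein, at 2.17, SURF1, a respiratory chain assembly factor, at 2.05, ECHDC2 at 2.02, BAIAP2 at 1.91 and UTF1 at 1.84. Here too Cy5 gave many more genes, 1397 against 43 in Cy3. The VCaP inhibitor array was weak in Cy5, with 48.9% of probes well above background against 67.3% on the VCaP DMSO array. Its median raw Cy5 intensity was 78.9 against 120, while Cy3 was level (55.6% and 56.1% of probes). How far this weak signal accounts for the Cy5 differences was not tested. As lists, and untested, genes of the amino acid and integrated stress response had a median of 0.004 in C4-2B, 0.36 in LAPC4 and 0.41 in VCaP, whose arrays share a slide within each line. The LAPC4 and VCaP medians lay above the 99.9th percentile of random lists. By label the median was -0.65 in DU145 (0.04th percentile) and 0.35 in PC3 (94.8th).

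The arrays labelled DU145 and PC3 differed most, in opposite directions and in the same genes. CAVIN1, a coat protein of caveolae, was higher by 9.27 with inhibitor under the DU145 label and lower under the PC3 label (-9.19). LY6K (8.55 and -8.59), TGFBI, a secreted matrix protein (6.93 and -6.87), MT1M, a metallothionein (5.91 and -5.83) and RFLNB (5.46 and -5.46) did likewise. TFF1, a trefoil factor (-9.01 and 8.79), INHBA, an activin subunit (-8.22 and 7.73) and FST, the activin antagonist follistatin (-7.67 and 7.38), went the other way. INHBB (-7.08) and GDF15 (-7.07) completed the list for DU145, and S100P (7.06) and TFF3 (6.94) that for PC3. In both channels 1104 genes were higher and 1161 lower in DU145, and 1356 and 1374 in PC3. The DMSO arrays of these labels lay on one slide and the inhibitor arrays on another, so a labelled treatment difference there is also a difference between slides.

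Because Cy3 and Cy5 differed within arrays, their ratio was tested as an addition chosen after the data were seen. Stress response genes had a median Cy5 over Cy3 above 0 on all 10 arrays, but near 0 on some: 0.86 (DMSO) and 0.99 (inhibitor) in C4-2B, 0.16 and 0.94 in LAPC4, 0.05 and 0.47 in VCaP, and by label 0.14 and 0.82 in DU145 and 0.78 and 0.06 in PC3. S phase genes had medians below 0 on 9 arrays, from -0.31 to -1.23, and of 0.22 on the VCaP DMSO array. The labels give no treatment for this direction. DDIT4, an mTORC1 inhibitor induced by ATF4 and by hypoxia (probe on chromosome 10, 73705369 to 73705428, hg18), was brighter by 1.19 ± 0.07 (log2, SE, 4 values; limma adjusted p = 0.0353). PYCR3, an enzyme of proline synthesis (chromosome 8, 144757545 to 144757604), was dimmer (-1.91 ± 0.09, adjusted p = 0.0353). ABHD11 stood at -1.59 ± 0.10, METTL1, a tRNA methyltransferase, at -1.40 ± 0.09 and HNRNPA3, an RNA-binding protein, at -1.29 ± 0.09. PRR13 (-1.26 ± 0.07), TOMM40L (-1.23 ± 0.07), TMEM177 (-1.05 ± 0.08), MRPL12, a mitochondrial ribosomal protein (-1.02 ± 0.07), and SLC39A4, a zinc importer (-0.90 ± 0.07), passed too. These are 10 of the 11 genes that passed. MTHFD1L, of mitochondrial folate metabolism (1.25 ± 0.11, adjusted p = 0.0575), PSAT1, of serine synthesis (1.09 ± 0.10, 0.0617), and SLC3A2 (0.81 ± 0.08, 0.0648) missed the threshold.

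Leaving out C4-2B, LAPC4 or VCaP gave 0 calls, and using only the arrays labelled with inhibitor also gave 0, against 15 on those labelled DMSO. A second probe of the same gene gave -1.33 for HNRNPA3, -1.17 for METTL1, -0.67 for ABHD11, -0.66 for PYCR3 and -0.29 for PRR13, so the size for the last 3 genes rests on 1 probe.

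Of the 29 lists reported, 4 were brighter and 4 dimmer in Cy5 by camera, each with adjusted p = 0.820 with an estimated correlation, and none by fry. The amino acid and integrated stress response was brightest (median 0.64, 19 of 20 members above 0, adjusted p = 1.64e-08), with 11 genes brighter adjusted over the list alone and 1 over all genes. SLC7A11 stood at 1.45 ± 0.24. Second probes of members, named here beyond the fixed rule, gave -0.099 for ASNS (0.984 by the probe used) and 0.096 for ATF3 (0.549). Those of SLC7A5, VEGFA, SLC3A2, STC2 and SLC7A11 gave 0.602 to 1.035. NRF2 targets, the genes of the oxidative stress response, had a median of 0.40 (14 of 17 above 0, adjusted p = 0.000842, 6 adjusted over the list alone), with GCLM, of glutathione synthesis, at 0.99 ± 0.17 and FTH1, of ferritin, at 0.51 ± 0.10. Hypoxia genes had 0.33 (17 of 19, adjusted p = 0.00422, 0 adjusted over the list alone), with KDM3A, a histone demethylase, at 0.55 ± 0.13 and VEGFA at 0.72 ± 0.17. Aryl hydrocarbon receptor targets had 0.41 (7 of 8, adjusted p = 0.0154, 3 adjusted over the list alone), with TIPARP at 0.52 ± 0.09. In VCaP the last 3 lists stood only at 0.09, 0.03 and 0.08, within the 99th percentile of random lists.

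On the dimmer side, all 24 S phase genes lay below 0 (median -0.73, adjusted p = 1.57e-07, 10 adjusted over the list alone). TK1, thymidine kinase, stood at -0.85 ± 0.15 and CDT1, a replication licensing factor, at -1.15 ± 0.22 (-0.65 by a second probe). Homologous recombination genes had -0.46 (18 of 19 below 0, adjusted p = 2.66e-05, 5 adjusted over the list alone), with BRCA1 at -1.06 ± 0.24 and FANCI at -1.08 ± 0.22, but in VCaP stood at -0.04 (0.28 on the DMSO array, -0.37 with inhibitor). Metallothioneins, which bind zinc and copper, had -1.16 (9 of 10 below 0, adjusted p = 0.00672, 0 adjusted over the list alone), with MT1X at -1.20 ± 0.38 and MT2A at -1.23 ± 0.41, but stood by label at -0.11 in DU145 and -0.06 in PC3. Androgen-repressed genes had -0.20 (11 of 11 below 0, adjusted p = 0.0364, 0 adjusted over the list alone), with UGT2B15, which inactivates androgens, at -0.60 ± 0.27, but VCaP carried this, at -0.62 against -0.04 in C4-2B, -0.14 in LAPC4 and by label -0.02 in DU145 and -0.01 in PC3. The rest did not pass, among them G2 and M phase genes at -0.16 (adjusted p = 0.138), MYC and ribosome biogenesis at -0.21 (0.151) and histone genes at -0.20 (0.208).

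**Figure D3:**
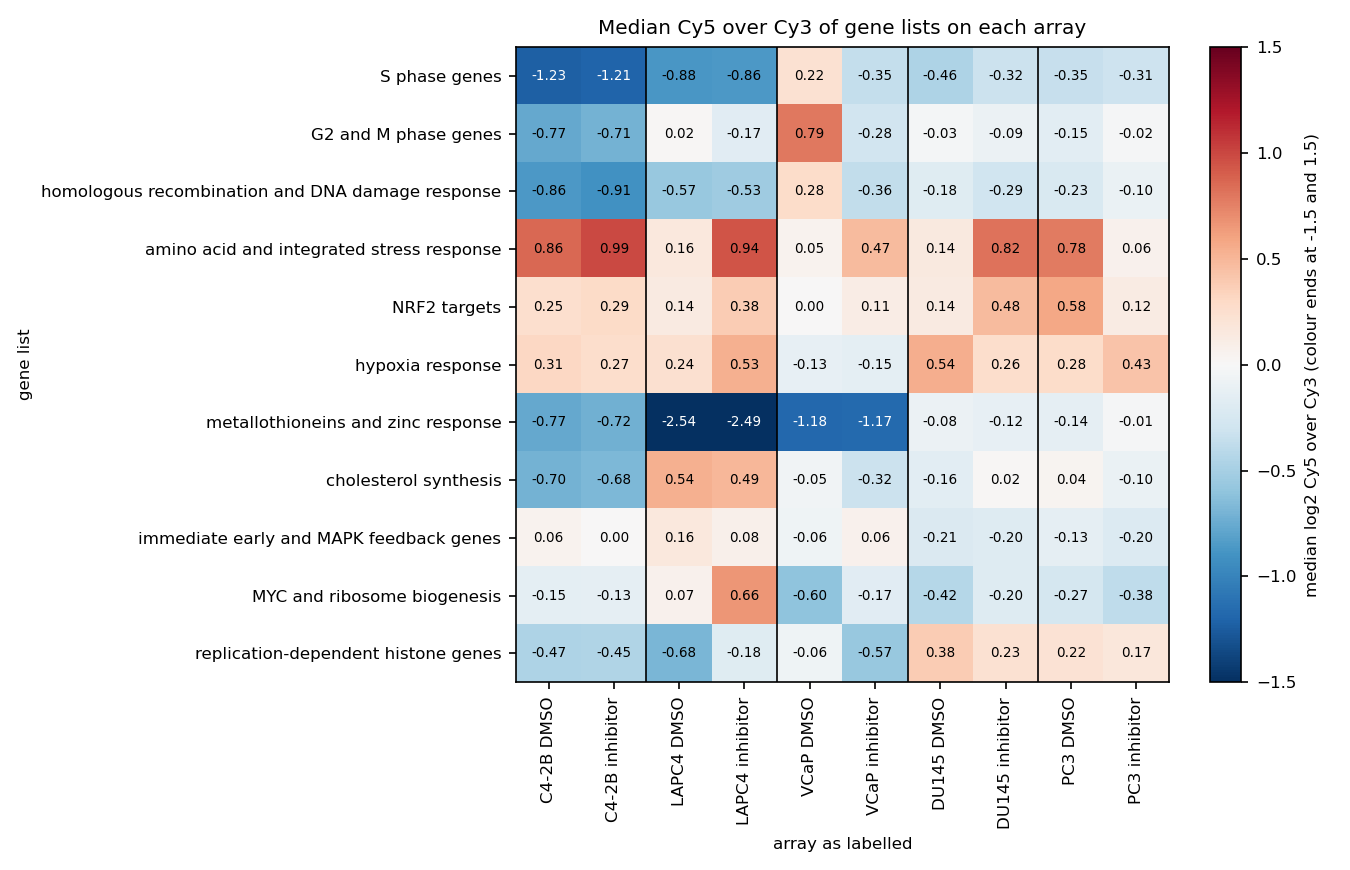
Median log2 Cy5 over Cy3 of 11 gene lists (vertical) on each of the 10 arrays (horizontal, by label); colour runs from -1.5 (dimmer in Cy5) to 1.5 (brighter). The stress response lies above 0 on each array, from 0.05 (VCaP with DMSO) to 0.99 (C4-2B with inhibitor).

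Lines differed in which programmes separated the channels, in values that rest on 2 arrays each and were not tested. C4-2B had the stress response at a median of 0.92, above all random lists. Among the brightest single genes in C4-2B, and not members of that list, GDF15, a stress cytokine, stood at 3.20 ± 0.02 (SD, 2 arrays). HMOX1, haem oxygenase, stood at 2.20 and FAS at 1.97, also outside that list. C4-2B had S phase genes at -1.22, with CDC45, a replicative helicase subunit, at -2.87 and RRM2, of ribonucleotide reductase, at -2.48. LAPC4 had metallothioneins at -2.52, with MT1G at -2.99, cholesterol synthesis at 0.61 with HMGCS1 at 1.63, and MYC and ribosome biogenesis at 0.42. CYP1A1, the classic aryl hydrocarbon receptor target, stood at 2.52 ± 0.91 there, and S100P at 2.84 ± 0.57. VCaP had the stress response at 0.32 and S phase genes at -0.04, the latter from arrays of opposite sign (0.22 with DMSO, -0.35 with inhibitor), with KMT5B, a histone H4 methyltransferase, at 2.79 ± 0.09, SOCS3 at 2.84 ± 2.39 and CREB3L4, a prostate-rich transcription factor, at -2.83. PYCR3 was among the most dimmed genes under both the DU145 label (-1.82) and the PC3 label (-1.53). Genes beyond 2-fold on both arrays of a line, brighter and dimmer, numbered 196 and 461 in C4-2B, 51 and 177 in LAPC4, 70 and 312 in VCaP, 16 and 27 in DU145 and 6 and 9 in PC3.

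Of the prostate genes, none passed in Cy5 over Cy3. TNK2 was 0.13 ± 0.07 (limma adjusted p = 0.369), KLK2 -0.30 ± 0.25, KMT2D 0.28 ± 0.14, WDR5 0.20 ± 0.21, FKBP5 -0.09 ± 0.07, TMPRSS2 -0.11 ± 0.17 and HOXB13 -0.38 ± 0.25. In VCaP HOXB13 stood at -1.35 and KLK2 at -1.28. A second HOXB13 probe gave -0.92 in C4-2B, -1.09 in LAPC4 and -1.94 in VCaP (mean of the 4 values -1.05), a second TNK2 probe -0.25 and a second KLK2 probe -0.10 (1.05 in C4-2B against -0.07, -1.42 in VCaP), so these values depend on the probe. KLK3 stood at 0.33 ± 0.09 (adjusted p = 0.144) by its brightest probe, but that probe read 15.2 to 16.3 on all arrays. The KLK3 probe matched by accession (chromosome 19, 56053565 to 56053624, hg18) read 13.44 and 13.41 in C4-2B, 10.71 and 9.91 in LAPC4 and 8.20 and 9.23 in VCaP, and 6.24 to 6.41 under the DU145 and PC3 labels. It gave a mean ratio of 0.03, and a labelled treatment difference of -0.02, but both means average opposite values. The ratios were 0.912 and -0.371 in LAPC4 and -0.878 and 1.052 in VCaP (DMSO, then inhibitor). The labelled differences were -0.799 in LAPC4 and 1.025 in VCaP, and -0.147 to -0.036 under the other labels.

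**Figure D4:**
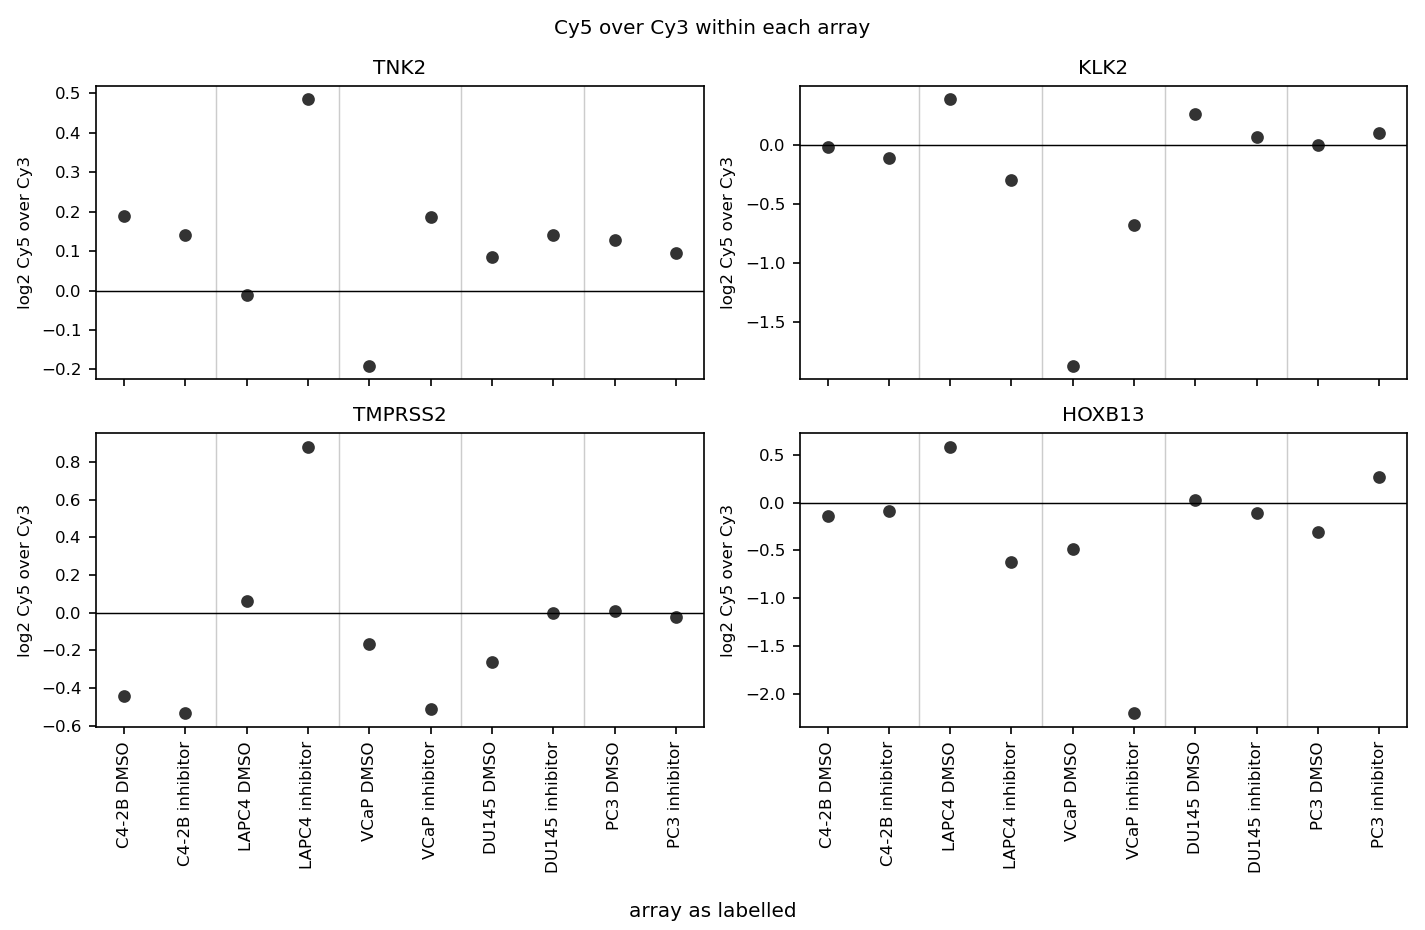
Log2 Cy5 over Cy3 of TNK2, KLK2, TMPRSS2 and HOXB13, 1 point per array, by line and treatment label. In VCaP the means were -1.35 for HOXB13 and -1.28 for KLK2.

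Over genes, the correlation of the labelled log2 differences ran from -0.903, for DU145 with PC3, to 0.263, for LAPC4 with VCaP, over the 10 pairs of lines (median 0.0147). The 7 pairs with DU145 or PC3 do not show how lines agree, since their labelled differences compare arrays that did not match. The other 2 pairs, both with C4-2B, whose arrays hardly differed, stood at 0.0480 with LAPC4 and -0.0670 with VCaP. Cy5 over Cy3 correlated positively in every pair, from 0.302 to 0.937 (median 0.399), the last again DU145 with PC3, where each label's mean holds 1 array of each matching pair, so that a high value follows from the crossing. Genes are not independent replicates, and no p is given for these 20 correlations.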

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

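The tests of a second probe and of other splits of the samples were set before their results were seen, and the other tests in this part were chosen only after.

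On the arrays of C4-2B, LAPC4 and VCaP Cy5 and Cy3 differed although the labels give both channels 1 RNA, as in CDC45 at -2.87 in C4-2B. A fixed dye bias of the probes would give the same ratios in every line. For cholesterol synthesis genes the lowest LAPC4 array median exceeded the highest of C4-2B by 1.17. That list was picked because its medians had opposite signs in these lines, so the gap is no independent test. The 2 lines also lay on different slides scanned on different dates, so a dye bias that varies between slides stays open. Of the 657 genes beyond 2-fold on both C4-2B arrays, 24.4% in LAPC4 and 28.2% in VCaP were beyond 2-fold the same way, and 88.4% and 84.9% had the same sign, so dye bias in part stays open for these genes. A fixed bias would also cancel between the arrays of a line within one dye. Genes beyond 2-fold numbered 1515 in Cy5 against 4 in Cy3 in LAPC4, and 1397 against 43 in VCaP. This argues against a fixed dye bias with 1 RNA per array as the whole source in these lines. C4-2B had 0 in either dye, and a bias or Cy5 signal that varies between arrays stays open. The Cy3 profiles of a line's arrays correlated by at least 0.186 more than Cy3 with Cy5 within an array, but dye bias alone would also raise Cy3 with Cy3, so this leaves a different RNA in each channel open. Which RNA that was, and whether it was treated, is not given by the labels, and no biological explanation was tested.

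The arrays labelled DU145 and PC3 matched across the labels. The lowest crossed correlation exceeded the highest correlation within a label by 0.766, as an exchange of the line labels between arrays of one slide would give. The matching arrays lay on different slides and carried different treatment labels, which argues against a slide batch and against an inhibitor effect alike in both lines as the source. The labelled effects correlated at -0.903 over genes, and 0.145% of the genes beyond 2-fold under both labels went the same way, but both values restate the crossed match and add no evidence. A candidate explanation is therefore that labels were exchanged on 1 of the 2 slides.

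Many genes had a like ratio of Cy5 over Cy3 in C4-2B, LAPC4, VCaP and the mean of the arrays labelled DU145 and PC3, among them PYCR3 and DDIT4. Where another probe was detected, its ratio was on median 45.2% of that of the probe used (quartiles 17.2% and 72.9%, 571 genes, the same sign in 499), which leaves dye bias of single probes open. The S phase genes lay below the 1st percentile of random lists in 4 of the 5 labelled lines, with VCaP at the 59.5th, and the stress response at or above the 99.96th in all 5. With all 29 lists counted, 5 to 11 per labelled line lay outside the 1st to 99th percentile, where 0.58 would by chance. This argues against a dye bias blind to gene function as the whole source, but does not exclude it. The random lists were matched on size and mean expression alone, and some lists share members. No list passed by camera with an estimated correlation or by fry. DU145 and PC3 are not independent here, and without a dye swap a share of dye bias stays open.

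Other splits of the samples could not exclude chance for the 5-line comparison, since it called 0 genes in limma (210 at an unadjusted p under 0.05) and any split gives as many. All 16 splits that part every pair gave as many, the highest other being 0. All 100 drawn splits into 5 and 5 did so too, with 890 at most, from splits that put both C4-2B arrays with a matching pair labelled DU145 and PC3 and 1 LAPC4 array, which points to a structure of the samples.

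Single arrays stood far from the others of their treatment in 4 of 36 sets of 5 values tested. The sets were levels and ratios of genes and shares of probes above background. Among like replicates chance picks out about 1 in 20 sets. These arrays are of different lines and the sets share arrays, so that rate is no measure of chance here. KLK2 had a log2 Cy5 over Cy3 of -1.873 on the VCaP DMSO array, against -0.023 to 0.384. TNK2 had 0.485 on the LAPC4 inhibitor array, against 0.094 to 0.187. A second detected TNK2 probe had the opposite sign on that array, -0.585 against -0.290 to 0.095, so the TNK2 value depends on the probe. The level of HOXB13 was 6.531 on the array labelled PC3 with DMSO, against 13.195 to 14.184, and 6.448 on that labelled DU145 with inhibitor, against 13.188 to 14.197. Those arrays form 1 pair that matched across the labels, so both HOXB13 values restate that match.

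Cholesterol synthesis had Cy5 over Cy3 medians of opposite sign in C4-2B and LAPC4 on both arrays of each, with means over the arrays of -0.692 and 0.515, a gap of -1.207, and this difference was not tested.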

How the results depend on the processing

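For Cy5 over Cy3, all fits with arrays left out by label, the authors' value table and 5 labelled-line means were chosen after the data were seen. The 5-line comparison gave 0 genes in limma under all 19 settings (210 at an unadjusted p under 0.05 as reported, 867 without the arrays labelled DU145 and PC3). The line label pairs DMSO with inhibitor in the fit, although the arrays labelled DU145 and PC3 did not match within their labels, and with no block for it the 5-line count was again 0 (32 unadjusted). Of the values for named genes, 412 kept their side of the threshold or, if untested, stayed within their spread. A further 40 passed only under another setting, and 88 no longer passed. Another 7 moved, as untested values beyond their spread or by a change of sign without a call. Among these 7 was TNK2 in Cy5 over Cy3, which kept its sign in 14 of 15 settings (lowest -0.05). None changed sign with a call.

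The 11 calls for Cy5 over Cy3 became 0 with no background correction, 375 with processed signals scaled at the 75th percentile, 491 among genes well above background on all arrays, 0 with trend and robust, 179 with array weights, 0 from the authors' value table, 1439 from 5 labelled-line means (where DU145 and PC3 count apart), 0 on the arrays labelled (R)-9bMS alone, 0 without the arrays labelled DU145 and PC3 and 0 to 0 in leave-one-out. The 1 list called over 5 lines became 0 with an estimated correlation, 2 with processed signals, 2 in Cy5, 0 in Cy3 and 0 to 7 in leave-one-out. Counts beyond 2-fold moved with processed signals to 3985 in DU145 (from 2265), 4607 in PC3 (from 2730) and 1 in LAPC4 (from 4), where Cy3 normalized alone gave 1, Cy5 normalized alone 1918 and no background correction 1. In VCaP they moved from 25 to 2057 with Cy5 normalized alone. Where fewer lines or other channels were used the construction accounts for the change in part, and otherwise the cause was not tested. The authors' value table holds ratios and was not run for levels. Each channel of each array had at least 48.9% of probes well above background.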

Other observations

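The values in this part were chosen only after the data were seen. ERG, the transcription factor that VCaP carries as a fusion with TMPRSS2, depended on the probe. The brightest ERG probe read 7.5 to 9.2 on all arrays, while another (chromosome 21, 38676351, hg18) read 10.01 and 9.35 in VCaP and at most 6.45 elsewhere. CAV1 and VIM separated the arrays labelled DU145 and PC3 (11.67 to 12.33 and 15.32 to 15.98) from C4-2B, LAPC4 and VCaP (at most 6.69 for CAV1), except that VIM also read 10.42 and 10.34 in C4-2B.

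Arrays of one line did not always share their Cy5 over Cy3. In VCaP the G2 and M phase genes had a median of 0.79 on the DMSO array and -0.28 on the inhibitor array, and S phase genes 0.22 and -0.35. In LAPC4 the integrated stress response had 0.16 and 0.94. In C4-2B the arrays differed little, with a correlation of 0.982 over genes against 0.537 in LAPC4 and 0.516 in VCaP. Under the crossed pairing of DU145 and PC3 labels, the stress response had 0.14 and 0.06 on the pair with HOXB13 signal and 0.82 and 0.78 on the other.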
